A study of Mus musculus with 6 samples.

How the data were processed

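The material was total RNA of the mouse glioma line GL261, taken 4 h after 1 uM sodium chloride (3 libraries) or 1 uM sodium propionate (3 libraries), per the labels. RNA was purified with an RNeasy Mini Plus kit and made into libraries with the TruSeq Stranded Total RNA LT Gold kit, per the labels' protocols. The submitters' processing notes name bcl2fastq, fastp, HISAT2 and StringTie and the mouse genome build mm10, with no role or order. Per the file headers, StringTie 2.1.1 estimated the abundance of a fixed set of transcript models in each library separately, and replicates were not pooled. The model set was common to the 6 libraries and held reference transcripts and transcripts assembled from reads, per the file headers. The strand setting of the alignment and the settings of the other tools are not given in the sources used here.

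The deposited values, per the file headers, are per-transcript coverage, FPKM and TPM, with no counts. TPM summed to 1000000 in each library, so depth was read from the ratio of coverage to FPKM. This gives the bases that StringTie counted, without reads that were removed or not aligned. For voom, read numbers were estimated from coverage, transcript length and the read length, which the smallest steps of coverage showed. The files held 157296 transcript models, of which 142491 were reference transcripts and 14805 were assembled. Of the assembled models, 11710 were joined to a reference gene and 3095 were not, and the models made 58324 genes. All but 1207 of the reference transcripts were found in GENCODE M21, an annotation of the same build, which gave gene names, gene classes and exons. Its transcript sequences gave GC content and the protein-coding genes that share no stretch of 31 bases with an annotated pseudogene. A listed 0 can be a failed estimate as well as a low level, because the quantifier divides reads between overlapping models.

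TPM were summed per gene. Genes whose longest transcript was under 200 nt were left out (396 with a mean of at least 1 TPM), because total RNA libraries measure them poorly. Each library was then scaled by the median over genes of its ratio to the geometric mean of the 6 libraries. The factors were 1.09, 0.990 and 1.03 for chloride 1, 2 and 3 and 0.971, 0.966 and 0.967 for propionate 1, 4 and 5. Genes with a mean of at least 1 TPM before scaling were tested, 15509 in all, with 11042 protein-coding genes, 2000 assembled loci and 1355 pseudogenes among them. Of these, 2066 (13.3%) shared an assembled locus with another reference gene, and 110 were listed at 0 in at least 1 library.

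Differences were tested two-sided on log2(TPM + 1) with limma 3.58.1 (lmFit and eBayes with a variance trend) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. A fold change on this scale understates the change of genes with low values. Transcripts with a mean of at least 1 TPM and a length of at least 200 nt, 35755 in all, were tested the same way. Files were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.

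Gene lists numbering 46 were written from general knowledge of propionate, stress and growth pathways and of the cell types that a glioma culture could hold. Lists with at least 3 tested members, 41 in all, were tested with camera of limma with a preset correlation of 0.01 and adjustment over the lists. Beside it stand camera with a correlation estimated per list, which called none, and fry, which called the immediate-early list. The lists of lymphoid, endothelial and neuronal markers had 1 tested member each, fibroblast and pericyte markers had 2 and erythroid markers 0, so these were not tested.

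The sample groups, tests, filters, gene lists, naming rule and the first group of alternative settings below were set before the data were examined. The naming rule took up to 10 genes per direction past the threshold with no overlap between groups, ranked by fold change. Where under 5 passed, it took the 8 genes with the smallest p in that direction, named as not past the threshold unless they were. In each list called by camera, and in the lists of propionate catabolism, short-chain fatty acid receptors and transporters and deacetylase inhibitor response, it took members past the threshold or else the 2 with the smallest p. Ffar2, Ffar3, Slc16a1, Pcca, Pccb, Acss2, Cdkn1a and H1f0 were named whatever their values. Models named by a number only, pseudogenes and small RNAs were counted but not named for the first parts of the rule, and Mir17hg was kept as a long transcript. Genes and transcripts named outside the rule are said to be so. Some genes that the rule or the text would name are not reported here.

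The gene test was checked on simulated data made from the real genes and their spread, with 200 genes changed in each of 5 draws. A single list of 30 genes shifted by 0.1 on the log2 scale had an unadjusted camera p under 0.05 in 20 of 20 draws, and an unshifted list in 0 of 20. No adjustment over lists was made there. Genes in those simulations vary independently, so neither value holds for lists whose members vary together.

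The first group of alternative settings was TPM as deposited, quantile normalization, TPM rescaled without mitochondrial and ribosomal RNA, pseudocounts of 0.1 and 0.5, no filter and a filter at 5 TPM, no variance trend, library weights, each library left out, voom on estimated read numbers, genes under 200 nt kept, an adjusted p of 0.1, and a fold of 1.5. For lists it also held the estimated correlation, fry and camera on ranks. Where a list's call is counted over settings, the main setting, the estimated correlation and fry are left out. Alternatives added after the data were seen were a term for the pair of libraries with fewer covered transcripts, the other 4 libraries alone, no gene listed at 0, reference transcripts alone, protein-coding genes alone, sums per assembled locus, genes with a GC value, and removal per library of a smooth trend in length and GC content.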

Results

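GL261 is a mouse glioma cell line. RNA was taken 4 h after addition of sodium propionate or of sodium chloride, which carries the same cation, each at 1 uM per the labels. That dose lies far below the millimolar doses of propionate usual in culture, and its unit could not be checked here. Propionate is a short-chain fatty acid made by gut bacteria. Each salt had 3 libraries of total RNA, numbered 1, 2 and 3 for chloride and 1, 4 and 5 for propionate in the sample titles. The deposited values held 9.41, 9.47 and 9.15 Gb of bases counted by StringTie for chloride 1, 2 and 3, and 9.33, 11.3 and 11.1 Gb for propionate 1, 4 and 5. The labels do not say that the libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical. All levels given for genes are scaled TPM, a relative transcript abundance, as mean ± SD with n = 3 per group unless stated. Fold changes are on the log2(TPM + 1) scale, propionate over chloride, with a standard error (SE).

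The libraries did not separate by salt. Pearson correlations of log2 values across genes were 0.97 to 0.99 between pairs of libraries. The first principal component held 31.6% of the variance and set chloride 3 (21.8) and propionate 1 (23.1) against the other 4 libraries, which lay between -26.3 and -4.38. The second held 24.8% and put these libraries at opposite ends, at 25.8 and -27.25. Their correlation with each other was 0.9772, within the range of their correlations with the other 4 libraries (0.9748 to 0.9819). The pair, singled out after the data were seen, had fewer transcripts with any coverage, 71452 in chloride 3 and 71192 in propionate 1, against 81178 to 82370 in the other 4. Because each salt had 1 of these libraries, a fit with a term for the pair could be made. Values from the other 4 libraries alone are given where they end a call or move a count by over 1.5 times. With TPM as deposited the median of all genes was -0.08 on the log2 scale, against 0.01 after scaling, so the sign of small differences depends on the scaling, and list medians with TPM as deposited stand against -0.08. Sense-intronic and unverified gene models, 270 in number, stood relative to protein-coding genes at -0.06, 0.10 and 0.26 in chloride 1, 2 and 3 and at -0.13, -0.11 and -0.09 in propionate 1, 4 and 5.

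The series asked which transcripts of GL261 cells respond to propionate. Of 15509 genes, Gm17201 was higher in propionate and none was lower past the threshold. Gm17201 (ENSMUSG00000090761) is an antisense gene of unknown function on the minus strand of chromosome 10, from 128391842 to 128395930 in mm10. It was listed at 0 in chloride 1, 2 and 3 and at 23.1, 13.5 and 15.9 TPM in propionate 1, 4 and 5 (limma, adjusted p = 0.00147). Its exon from 128391842 to 128392073 lies inside an exon of Ankrd52 on the other strand, and its exon from 128395406 to 128395930 lies outside Ankrd52 exons. Ankrd52 itself stood at 31.4 ± 3.69 TPM in chloride and 30.5 ± 5.41 in propionate. As use of strand in the quantification is not given in the sources used here, the Gm17201 value is uncertain. The gene is named although it falls outside the naming rule for numbered gene models, and was chosen after its values were seen. Its call was lost with no filter on low values (limma adjusted p = 0.0586) and with voom (0.218), over a range of 2.86e-05 to 0.218.

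**Figure D1:**
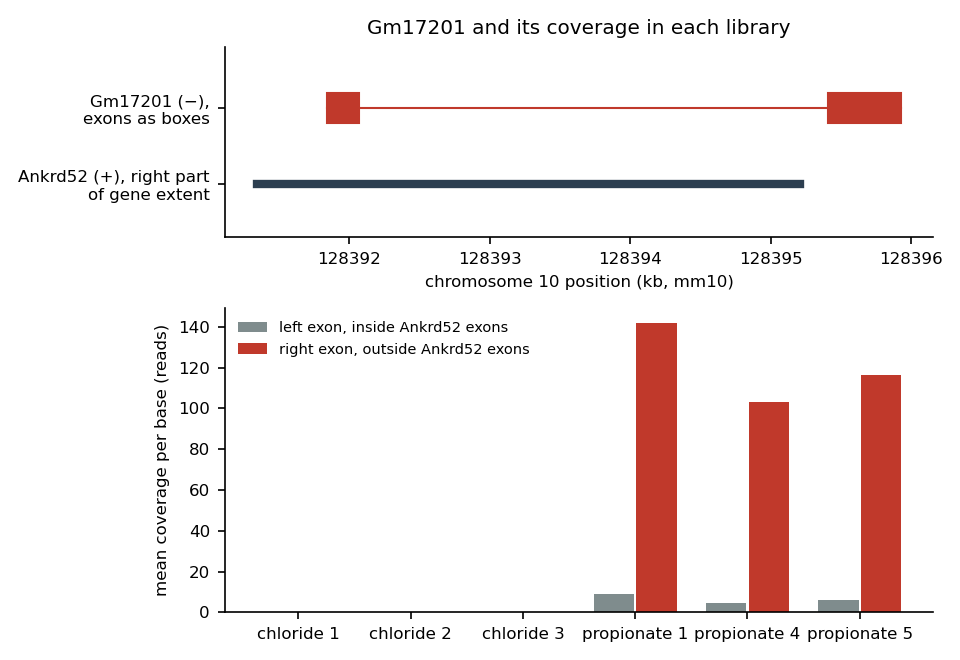
Upper panel, the exons of Gm17201 on chromosome 10 (kb, mm10) beside the right part of the reference extent of Ankrd52 on the other strand. Lower panel, mean coverage per base (reads) of each Gm17201 exon in each library, listed at 0 in the 3 chloride libraries and with a propionate mean of 120 for the right exon and 6.49 for the left.

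By limma, 0 genes were lower past adjusted p 0.05, with 463 lower and 335 higher at unadjusted p under 0.05. These 798 genes compare with 775 expected by chance, but the count depended on the libraries and settings. It ran from 475 without chloride 3 to 1020 without propionate 1, and was 1342 with the pair term and 2192 with library weights. Other splits of the libraries that parted chloride 3 and propionate 1, as the real split does, gave 322 to 514. Splits that kept these libraries together gave 479 to 1833. The groups did not overlap for 1822 genes (11.7%), where chance gives 10%. The voom variant of limma on estimated read numbers called 0 genes in either direction, with 826 at unadjusted p under 0.05. Limma called 4 genes without propionate 1 and 6 with the 4 better-covered libraries. The median SE was 0.11 on the log2 scale, and the 95% interval lay within 2-fold either way for 93.7% of genes and within 1.5-fold for 78.0%. In simulated data with 200 changed genes among 15509, limma recovered 38.5% of 1.5-fold, 73.4% of 2-fold and 91.1% of 4-fold changes, and 0% at the only smaller size simulated. At this spread and n = 3, changes under 1.5-fold were mostly not recovered, and the effect of depth was not tested.

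Among the genes with the smallest p that were higher in propionate, none but Gm17201 passed the threshold. Rnaset2a, which encodes a secreted and lysosomal ribonuclease, stood at 16.1 ± 0.92 TPM in chloride and 28.4 ± 1.30 in propionate. Its log2 difference was 0.78 (SE 0.07, limma adjusted p = 0.0764), with all propionate libraries above all chloride libraries. Its near-identical copy Rnaset2b stood at 34.9 ± 2.30 and 34.0 ± 1.89, and reads shared between the copies leave Rnaset2a uncertain. Spry1, a feedback inhibitor of receptor tyrosine kinase signalling, stood at 0.850 ± 0.101 TPM in chloride and at 2.05, 8.15 and 7.77 in propionate 1, 4 and 5 (log2 1.76, SE 0.41, limma adjusted p = 0.912). Klhdc3 stood at 3.13 ± 0.730 and 5.96 ± 1.14, Anxa11 at 4.84 ± 0.605 and 7.32 ± 1.08, and the centrosomal gene Cdk5rap2 at 26.6 ± 2.25 and 34.7 ± 1.35. The ubiquitin-conjugating enzyme gene Ube2w stood at 22.3 ± 1.55 and 29.3 ± 0.544, and Snapin at 24.3 ± 0.489 and 29.6 ± 1.81 (limma adjusted p = 0.912 for these 5 genes). Klhdc3 shares its locus with Rrp36, and Ube2w with Eloc. Summed over the locus, Klhdc3 stood at 16.5 ± 1.92 and 20.2 ± 1.20 (log2 0.28) and Ube2w at 63.9 ± 1.78 and 69.8 ± 4.59 (log2 0.12), and Cdk5rap2 was lower by sign with voom (log2 -0.11).

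For Rnaset2a, limma gave adjusted p under 0.05 in 5 settings, among them 0.0450 with a mean of at least 5 TPM and 0.00284 with library weights, over a range of 0.00284 to 0.941. Its log2 difference was 0.37 with voom and 1.62 with reference transcripts alone, and those of Ube2w were 0.07 and 0.77, while Anxa11 was 0.14 with voom and Klhdc3 0.47 with library weights. Spry1 passed without propionate 1 (adjusted p = 0.00909) and with the 4 better-covered libraries (0.013), but shares its locus with Gm43820, and the summed locus stood at 10.3 ± 0.493 and 13.8 ± 1.46 TPM (limma adjusted p = 0.923).

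The lower genes with the smallest p included 3 long noncoding RNAs, and none passed. Rsrp1 stood at 93.4 ± 3.88 TPM in chloride and 75.5 ± 2.16 in propionate (log2 -0.30, SE 0.06, limma adjusted p = 0.912). Slc15a2, a peptide transporter, stood at 19.2 ± 1.02 and 14.7 ± 0.470. Lncpint, a p53-induced long noncoding RNA, stood at 19.5 ± 1.14 and 14.4 ± 1.21. Mir17hg, the long host transcript of the microRNA cluster it is named for, stood at 18.3 ± 1.4 and 12.4 ± 1.8, and Dancr, a snoRNA host, at 12.9 ± 0.430 and 9.87 ± 0.730. Erdr1 stood at 25.2 ± 1.64 and 17.5 ± 2.19, Btbd7 at 23.8 ± 1.09 and 19.2 ± 0.743, and Gps2, a corepressor subunit, at 6.10 ± 1.34 and 3.33 ± 0.456. The adjusted p by limma was 0.912 for each of the 8, and the propionate libraries lay below the chloride libraries for each. The log2 difference of Btbd7 was -0.29, but -0.10 with voom, that of Mir17hg -0.53, but -0.35 with library weights, and that of Rsrp1 was -0.48 with reference transcripts alone. Mir17hg, Dancr, Lncpint, Erdr1 and Gps2 share a locus with other transcripts, and summed over the locus Mir17hg stood at 22.6 ± 1.79 and 24.5 ± 11.9 TPM and Gps2 at 16.5 ± 0.553 and 13.15 ± 0.899 (log2 -0.31).

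**Figure D2:**
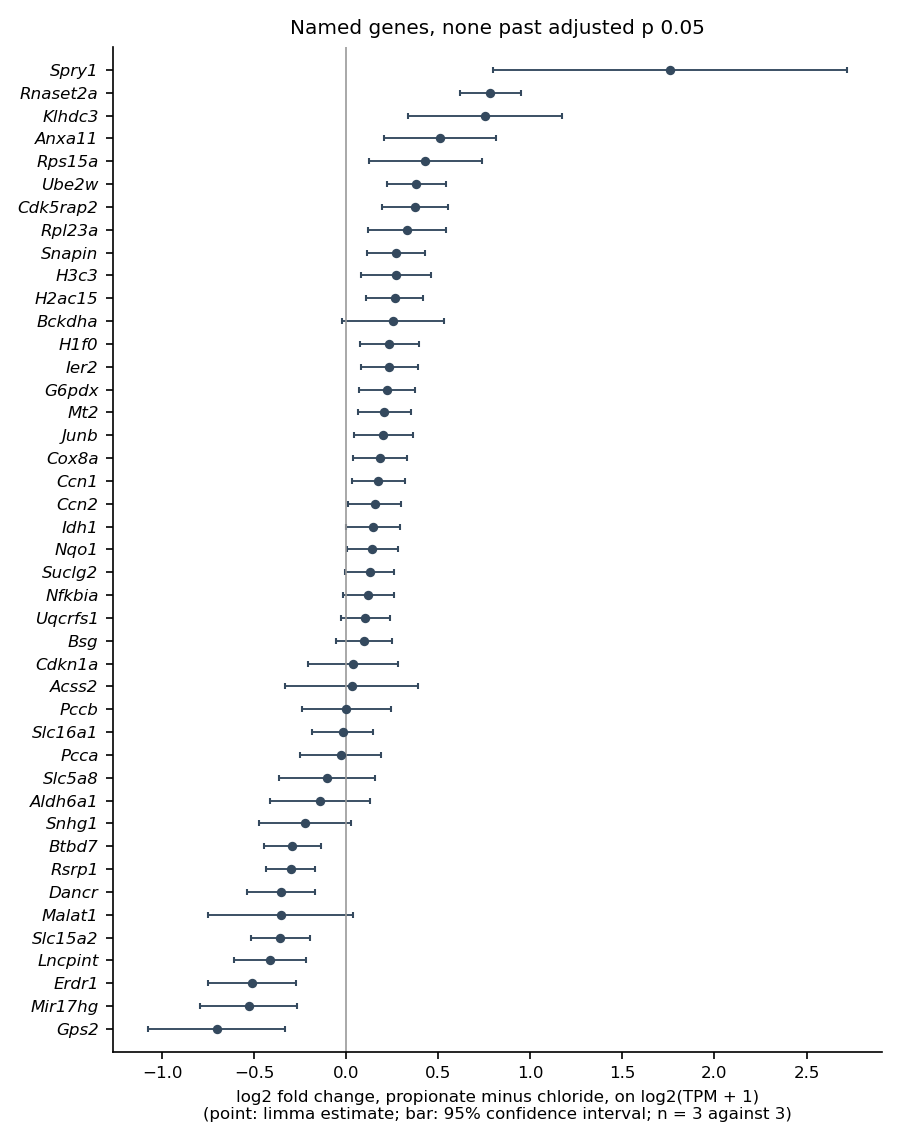
Log2 fold change of the named genes that did not pass the threshold, propionate minus chloride on log2(TPM + 1), with the limma estimate as a point and the 95% interval as a bar (n = 3 against 3). Estimates run from -0.70 for Gps2 to 1.76 for Spry1, whose interval is wide, and the intervals, which are not adjusted for the number of genes, span 0 for genes such as Slc16a1, Pcca and Pccb.

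Genes that sense, carry or break down propionate showed no difference past the threshold. The short-chain fatty acid receptor genes Ffar2 and Ffar3 were listed at 0 in each of the 6 libraries. Slc16a1, a monocarboxylate transporter, stood at 93.6 ± 3.59 TPM in chloride and 92.4 ± 6.73 in propionate (log2 -0.02, 95% interval -0.19 to 0.15). Its chaperone Bsg stood at 696 ± 20.8 and 745 ± 37.7, and the sodium-coupled carrier Slc5a8 at 7.37 ± 0.959 and 6.76 ± 0.584. Pcca and Pccb, the subunits of propionyl-CoA carboxylase, stood at 7.57 ± 0.643 and 7.38 ± 0.455, and at 7.08 ± 0.243 and 7.11 ± 0.902. Acss2, an acyl-CoA synthetase, stood at 2.27 ± 0.398 and 2.33 ± 0.359. Bckdha, of branched-chain keto acid breakdown, stood at 11.9 ± 1.28 and 14.4 ± 1.96, and Aldh6a1, which forms propionyl-CoA, at 3.69 ± 0.470 and 3.23 ± 0.0593. Of 19 tested genes of propionate catabolism, 11 were higher and 8 lower by sign, with a median log2 difference of 0.02 (camera adjusted p = 0.632). Of 5 tested receptors and transporters, 1 was higher and 4 lower by sign (median -0.02, camera adjusted p = 0.751). No member of either list passed over all genes or adjusted over the list alone by limma, where 0 of the 19 and 0 of the 5 had unadjusted p under 0.05. The signs for Slc16a1, Pcca, Pccb, Acss2 and Bsg changed with the scaling or the libraries used.

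Genes known to respond to histone deacetylase inhibitors lay slightly higher in propionate as a group by camera. Of 17 tested, 14 were higher and 3 lower by sign, with a median log2 difference of 0.12 (camera adjusted p = 0.00765, and adjusted p = 0.524 with an estimated correlation). H1f0, a linker histone gene, stood at 131 ± 9.73 TPM and 154 ± 4.41 (log2 0.23, SE 0.07, limma adjusted p = 0.912). Mt2, a metallothionein gene, stood at 78.0 ± 0.556 and 90.2 ± 5.55. Cdkn1a, the cell-cycle inhibitor p21, stood at 21.2 ± 2.34 and 21.8 ± 2.21 (log2 0.04, 95% interval -0.21 to 0.28), and was lower by sign with TPM as deposited. The deacetylase and acetyltransferase genes themselves were 10 higher and 16 lower by sign (median -0.02, camera adjusted p = 0.632). No member of either list passed over all genes or adjusted over the list alone by limma, and 3 inhibitor-responsive genes were higher and 1 lower at unadjusted p under 0.05. The camera call was lost without chloride 2 (adjusted p = 0.0630), without propionate 1 (0.0618, median 0.07) and with the 4 better-covered libraries (0.139), and the median was 0.07 without chloride 3. It was present in 14 of 23 settings, and was also lost with TPM as deposited (0.113, median 0.03), mitochondrial and ribosomal RNA left out (0.126), quantile normalization (0.0929, median 0.04), library weights (0.0578), reference transcripts alone (0.146) and the length and GC trend removed (0.0725).

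Immediate-early genes, which growth factors and stress induce within minutes, lay higher in propionate as a group. Of 27 tested, 24 were higher and 3 lower by sign, with a median log2 difference of 0.12 (camera adjusted p = 1.05e-05, and adjusted p = 0.220 with an estimated correlation). The median of the list per library, relative to the mean of the 6, was -0.09, -0.03 and -0.07 in chloride 1, 2 and 3, and 0.04, 0.08 and 0.05 in propionate 1, 4 and 5. Ier2 stood at 32.3 ± 2.23 TPM and 38.1 ± 0.754 (log2 0.23, SE 0.07), and Junb, an AP-1 subunit, at 87.1 ± 5.85 and 100.3 ± 4.35 (log2 0.20, SE 0.07). No member passed over all genes (limma adjusted p = 0.912 for both) or adjusted over the list alone, where the lowest value was 0.207. Among all lists, only this was called by fry, which tests whether the genes of a list move one way on balance (adjusted p = 0.0134). Camera with the preset correlation called it in each of 23 settings, with adjusted p from 1.34e-06 to 0.00189, and the median was 0.03 with TPM as deposited.

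Targets of Wnt, TGF-beta and YAP signalling, which share Ccn1 and Ccn2 with the immediate-early list, and glucocorticoid targets, which share Dusp1 with it, were also called by camera. Among 15 targets of Wnt, TGF-beta and YAP signalling, 13 were higher and 2 lower by sign (median 0.03, but -0.06 with TPM as deposited; camera adjusted p = 0.0375, and adjusted p = 0.524 with an estimated correlation). Its leading members were the matrix genes Ccn1, at 453 ± 15.9 and 511 ± 19.2 TPM, and Ccn2, at 567 ± 14.9 and 632 ± 28.9. Among 10 glucocorticoid targets, 9 were higher and 1 lower by sign (median 0.09, but -0.0070 with TPM as deposited; camera adjusted p = 0.0146, and adjusted p = 0.524 with an estimated correlation). It was led by Mt2, shared with the deacetylase list, and by the NF-kappaB inhibitor Nfkbia, at 32.1 ± 1.36 and 34.9 ± 0.702 TPM. No member of either list passed over all genes or adjusted over the list alone by limma. The Wnt, TGF-beta and YAP call was present in 10 of 23 camera settings. It was lost without chloride 1 (adjusted p = 0.0939), propionate 1 (0.0859) or propionate 5 (0.224), with the 4 better-covered libraries (0.131), TPM as deposited (0.280), mitochondrial and ribosomal RNA left out (0.296), quantile normalization (0.345), the pair term (0.0589), no variance trend (0.0610), reference transcripts alone (0.352), the length and GC trend removed (0.0592), genes with a GC value alone (0.0524) and protein-coding genes alone (0.0618), and the median ran from 0.04 to 0.10 as single libraries were left out. The glucocorticoid call was present in 17 of 23, and was lost without chloride 3 (0.150) or propionate 4 (0.0726), with the 4 better-covered libraries (0.131), TPM as deposited (0.113), mitochondrial and ribosomal RNA left out (0.126) and the length and GC trend removed (0.0592).

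Replication-dependent histone genes lay higher in propionate as a group by camera, with the highest level in propionate 1. Of 47 tested, 44 were higher and 3 lower by sign, with a median log2 difference of 0.16 (camera adjusted p = 1.53e-10, and adjusted p = 0.524 with an estimated correlation). H2ac15 stood at 402 ± 23.7 TPM in chloride and 482 ± 16.5 in propionate, and H3c3 at 414 ± 32.1 and 498.5 ± 31.4. The list's median per library was -0.13, -0.02 and -0.10 in chloride 1, 2 and 3, and 0.27, 0.01 and -0.04 in propionate 1, 4 and 5, so that propionate 5 lay below chloride 2. Without propionate 1 the median difference was 0.07 (camera adjusted p = 0.00936), and with the 4 better-covered libraries it was 0.06 (0.0244). It was 0.06 with TPM as deposited, 0.09 with quantile normalization, 0.07 with library weights and 0.08 with the length and GC trend removed. No member passed over all genes or adjusted over the list alone by limma, and reads shared between near-identical histone copies leave single members uncertain.

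Ribosomal protein and respiratory chain genes lay higher as groups by camera, by still smaller amounts. Of 77 ribosomal protein genes, 71 were higher and 6 lower by sign, with a median log2 difference of 0.09, but -0.0064 with TPM as deposited (camera adjusted p = 2.6e-07, and adjusted p = 0.536 with an estimated correlation). Rpl23a stood at 786 ± 84.2 TPM and 986 ± 38.7, and Rps15a at 250 ± 29.3 and 338 ± 47.9, both uncertain because processed pseudogenes share their reads. Of 52 nuclear genes of oxidative phosphorylation, 50 were higher and 2 lower by sign (median 0.08, but -0.02 with TPM as deposited; camera adjusted p = 1.11e-06, and adjusted p = 0.524 with an estimated correlation). Cox8a stood at 272 ± 5.28 and 309 ± 18.7, and Uqcrfs1 at 105 ± 3.86 and 113 ± 3.88. Of 30 genes of the tricarboxylic acid cycle and pyruvate use, 25 were higher and 5 lower by sign (median 0.05, but -0.05 with TPM as deposited; camera adjusted p = 0.0173, and adjusted p = 0.524 with an estimated correlation). Idh1 stood at 29.4 ± 0.322 and 32.7 ± 1.81, and Suclg2 at 37.98 ± 1.02 and 41.6 ± 1.41. The 14 mitochondrially encoded genes were 3 higher and 11 lower by sign (median -0.02, camera adjusted p = 0.445), and were called as lower with quantile normalization (0.0267) and without chloride 2 (0.0496). No member of these 4 lists passed over all genes or adjusted over the list alone by limma.

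The ribosomal median per library was -0.02, 0.02 and -0.15 in chloride 1, 2 and 3, and -0.02, 0.11 and 0.06 in propionate 1, 4 and 5, so that propionate 1 lay below chloride 1 and 2. The median of the respiratory chain genes was -0.03, -0.0017 and -0.09 in chloride, and 0.0046, 0.08 and 0.03 in propionate. The ribosomal difference was 0.05 without chloride 3 (camera adjusted p = 0.0186), 0.14 without propionate 1 and 0.06 with the length and GC trend removed. Both calls were absent with quantile normalization (0.429 and 0.239). The tricarboxylic acid call was present in 13 of 23 settings, with a median of 0.08 without chloride 1. It was absent without chloride 2 (0.0630), chloride 3 (0.150) or propionate 4 (0.102), and with the 4 better-covered libraries (0.131), quantile normalization (0.629), TPM as deposited (0.693), mitochondrial and ribosomal RNA left out (0.711), reference transcripts alone (0.497), a mean of at least 5 TPM (0.0785) and library weights (0.0578).

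By camera, NRF2 targets of the oxidative stress response lay higher as a group and nuclear-retained RNAs lower, with calls that depended on the settings. Of 28 NRF2 targets, 22 were higher and 6 lower by sign (median 0.09, but -0.0098 with TPM as deposited; camera adjusted p = 0.00765, and adjusted p = 0.524 with an estimated correlation). G6pdx, the entry enzyme of the pentose phosphate pathway, stood at 86.2 ± 4.87 TPM and 100.6 ± 4.06, and the quinone reductase gene Nqo1 at 69.5 ± 2.54 and 76.8 ± 3.22. Of 6 nuclear-retained or short-lived long noncoding RNAs, 1 was higher and 5 lower by sign (median -0.18, camera adjusted p = 0.0394, and adjusted p = 0.536 with an estimated correlation). Malat1 stood at 540 ± 141 and 413 ± 16.9, with chloride 3 at 699, and was higher by sign with reference transcripts alone. Snhg1 stood at 234 ± 21.5 and 201 ± 24.1. The median of this list per library was -0.04, 0.12 and 0.14 in chloride 1, 2 and 3, and -0.225, 0.04 and -0.09 in propionate 1, 4 and 5, so that the groups overlapped. The sense-intronic and unverified models also lay lower in propionate, with a median log2 difference of -0.216 relative to protein-coding genes. No member of either list passed over all genes or adjusted over the list alone by limma. The NRF2 call was present in 17 of 23 camera settings, and was lost without chloride 3 (adjusted p = 0.232, median 0.05) or propionate 4 (0.0548), with the 4 better-covered libraries (0.190), TPM as deposited (0.117), mitochondrial and ribosomal RNA left out (0.126) and quantile normalization (0.175). The nuclear call was present in 11 of 22, and was lost without chloride 2 (0.165), chloride 3 (0.0630) or propionate 1 (0.436, median -0.09), with the 4 better-covered libraries (0.383), no filter on low values (0.269, median -0.01), a mean of at least 5 TPM (0.0611), no variance trend (0.0610), library weights (0.183), ranks (0.0612), reference transcripts alone (0.288) and the length and GC trend removed (0.0850).

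**Figure D3:**
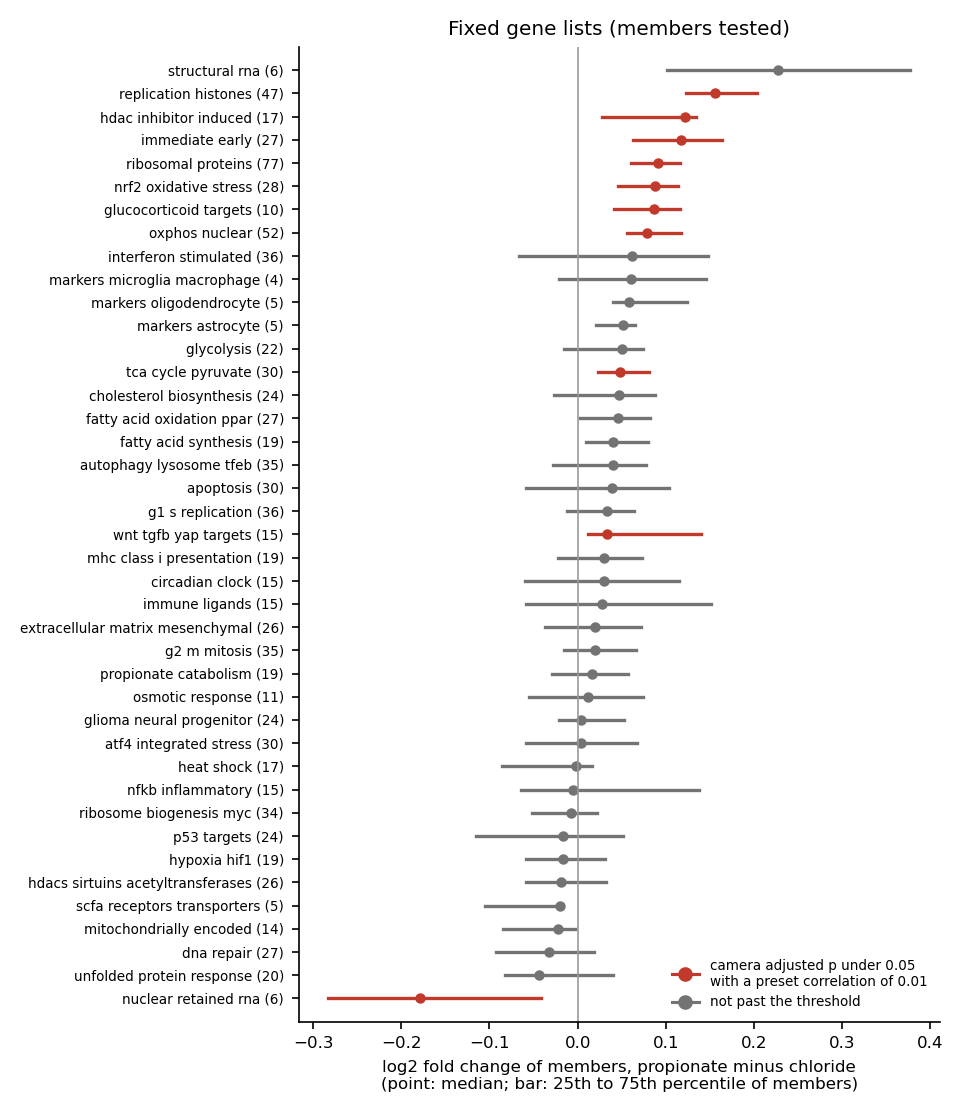
Log2 fold change of the members of each fixed gene list with at least 3 tested members (number in brackets), propionate minus chloride, with the median as a point and the interquartile range of members as a bar. Red lists were called by camera with a preset correlation of 0.01 and have medians between -0.18 and 0.16; none was called with an estimated correlation, and with TPM as deposited the medians of the NRF2, tricarboxylic acid, oxidative phosphorylation, ribosomal protein, Wnt and glucocorticoid lists were below 0 but above the median of all genes (-0.08).

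The other lists of stress, immune, lipid and growth genes were not called by camera with the 6 libraries and the main settings. Interferon-stimulated genes were 21 higher and 15 lower by sign (camera adjusted p = 0.328), antigen presentation genes 13 and 6 (0.391), NF-kappaB genes 7 and 8 (0.631), and immune ligands 9 and 6 (0.328). ATF4 targets were 15 and 15 (0.937), unfolded protein response genes 7 and 13 (0.399), heat shock genes 8 and 9 (0.328), osmotic response genes 7 and 4 (0.716), and hypoxia targets 7 and 12 (0.631). Cholesterol synthesis genes were 15 and 9 (0.212), fatty acid synthesis genes 15 and 4 (0.212), fatty acid oxidation genes 20 and 7 (0.0981), and glycolysis genes 14 and 8 (0.391). Genes of G1/S and replication were 24 and 12 (0.189), of mitosis 21 and 14 (0.328), of DNA repair 9 and 18 (0.253), p53 targets 11 and 13 (0.873), and apoptosis genes 17 and 13 (0.403). Ribosome biogenesis genes were 16 and 18 (0.585), circadian genes 8 and 7 (0.391), and lysosomal genes 22 and 13 (0.253). Glioma and neural progenitor genes were 14 and 10 (0.584), and matrix genes 17 and 9 (0.391). No member of any of these lists passed over all genes or adjusted over the list alone by limma, and camera with an estimated correlation called none of them. Camera called interferon-stimulated genes as higher without chloride 2 (adjusted p = 6.14e-05), without propionate 1 (0.0278) and with library weights (0.0261), and antigen presentation genes as higher without chloride 2 (0.0496), while the interferon median was below 0 without chloride 3 (-0.03) or propionate 5 (-0.01). It called unfolded protein response (0.0165), heat shock (0.00531) and ribosome biogenesis genes (0.0162) as lower with quantile normalization, DNA repair genes as lower with TPM as deposited (0.0466) and with mitochondrial and ribosomal RNA left out (0.0467), and genes of fatty acid synthesis (0.0450), fatty acid oxidation (0.0305) and G1/S and replication (0.0452) as higher with no filter on low values.

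Transcripts were tested as a separate measure, since StringTie estimates each isoform. Of 35755 transcripts, 8 were higher and 5 lower in propionate past the threshold by limma. Among those lower was the Hspa5 transcript ENSMUST00000028222, from 219 ± 10.1 TPM in chloride to 17.0 ± 1.24 in propionate (adjusted p = 0.00179). Among those higher were the Ptp4a2 transcript ENSMUST00000030578, from 12.6 ± 0.272 to 103 ± 15.5 (adjusted p = 0.0173), the Vdac2 transcript ENSMUST00000172727, from 22.5 ± 1.45 to 92.1 ± 9.51 (adjusted p = 0.0241), and the Cryab transcript ENSMUST00000217475, from 0.0483 ± 0.0731 to 143 ± 71.4 (adjusted p = 0.0352). Summed over their transcripts these genes differed little. Hspa5, the main chaperone of the endoplasmic reticulum, stood at 486 ± 15.9 and 470 ± 54.7 TPM, Ptp4a2 at 125 ± 6.41 and 122 ± 12.2, Vdac2 at 229 ± 13.9 and 249 ± 9.81, and Cryab at 601 ± 66.8 and 619 ± 33.9. The Hspa5 transcript ENSMUST00000100171, which has the same end as the called one, went the other way (log2 0.86, limma adjusted p = 0.345). Whether isoform use or the division of reads between overlapping models differed was not tested. Other called transcripts belonged to Taf12, Gm17201, Vapa, Pxdc1 and Washc2, higher, and to Cdk5rap2, Gnb2 and Tipin, lower. Of the 13 genes only Gm17201 passed in the gene test. These transcripts are outside the naming rule and were chosen after their values were seen. Of the 13, 4 were listed at 0 in each library of a group, and the count ranged from 2 to 33 as single libraries were left out. Among tested transcripts, 36 were listed at 0 throughout 1 group and at 1 TPM or more throughout the other. The same count was 34 to 69 in other splits of the libraries. Limma called 1 transcript with a term for the pair of libraries with fewer covered transcripts. Other splits of the 6 libraries gave 11 to 17 where they parted this pair, as the real split does, and 28 to 48 where they did not.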

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

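The settings with the 4 better-covered libraries, the pair term, no listed zeros, reference transcripts, locus sums and the length and GC trend were chosen after the data were seen. No paired analysis was possible because the groups share only replicate number 1. Of 27 settings, 17 kept the count of genes within 1.5 times of 1, as did 20 of 25 settings for lists and 7 of 17 for transcripts. These are totals and need not hold the same members. With protein-coding genes alone, which leaves out Gm17201, the gene called was Rnaset2a. Gm17201 had limma adjusted p under 0.05 in 20 of 22 settings, from 2.86e-05 to 0.218. These settings reuse the same listed zeros of the chloride libraries, which have no spread. Its log2 difference was 4.18 in the main setting, 5.13 with a pseudocount of 0.5, 7.42 with 0.1 and 10.2 with voom. Of 1039 values of 44 named genes under other settings, 999 kept their direction and side of the threshold, 6 became called, 2 lost the call and 32 turned. Many of these genes were named for a small p in the same data, and all but Gm17201 were uncalled in the main setting. Most values could therefore hardly change, and the count is no test of the differences. In simulated data at the observed spread with n = 3, changes under 1.5-fold were mostly not recovered. The libraries held 9.15 to 11.3 Gb of counted bases, and the effect of depth was not tested.

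The count of genes was 0 with no filter on low values, 0 with voom, and 0 with genes listed at 0 left out, which removes Gm17201 by construction. It was 2 with a mean of at least 5 TPM, 2 with library weights, 2 with the length and GC trend removed, 2 with locus sums and 2 at an adjusted p of 0.1, which is a looser threshold. With the 4 better-covered libraries it was 6. Leaving out each library gave 1 to 4 genes, with 4 without propionate 1. The count of lists was 0 with an estimated correlation, 1 with fry, 4 with the 4 better-covered libraries, 6 with reference transcripts alone and 6 with the length and GC trend removed, and 7 to 11 as each library was left out. Of the 10 lists, 4 remained called with quantile normalization, which called 8, and 5 with TPM as deposited or without mitochondrial and ribosomal RNA, which called 7 each. The count of transcripts was 3 with no filter, 5 with at least 5 TPM, 23 with no variance trend, 21 with library weights and 1 with the pair term. It was 2 to 33 as each library was left out, with 6 without chloride 2, 33 without propionate 1, 5 without propionate 4, 2 without propionate 5 and 8 without chloride 3. Apart from the listed zeros and the looser threshold, the cause was not tested.

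These log2 differences turned, each for a gene that did not pass, and the cause was not tested. With voom Cdk5rap2 was -0.108, Pcca 0.00603 and Pccb 0.0315. With reference transcripts Malat1 was 1.11. With TPM as deposited Bsg was -0.00145, Acss2 -0.0368 and Cdkn1a -0.0570, and without mitochondrial and ribosomal RNA they were -0.00494, -0.0395 and -0.0604. With library weights Slc16a1 was 0.0460, Pcca 0.0306, Acss2 -0.0745 and Cdkn1a -0.0414. With the 4 better-covered libraries Slc16a1 was 0.0228, Pcca 0.0368, Acss2 -0.0169 and Cdkn1a -0.0623. Slc16a1 was 0.00682 with the length and GC trend removed, and Pccb was 0.0115 with quantile normalization and 0.000312 with short genes kept. As each library was left out, Slc16a1 ran from -0.0581 to 0.0405, Pcca from -0.0935 to 0.0138, Pccb from -0.0838 to 0.0763, Acss2 from -0.0726 to 0.111 and Cdkn1a from -0.0421 to 0.118.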

Other observations

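The depth test, the test of sequence shared with pseudogenes, the intron-derived RNA test, the length and GC test of the immediate-early list, the counts over other splits and the values with the 4 better-covered libraries were chosen after the results were seen.

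Markers of neural cell types were detected in part. Of 29 glioma and neural progenitor genes 24 reached a mean of 1 TPM, as did 5 of 10 oligodendrocyte, 5 of 10 astrocyte and 4 of 18 microglia and macrophage markers. Mbp, a myelin protein gene, stood at 209 ± 20.9 scaled TPM in chloride and 218 ± 25.5 in propionate (SD, n = 3). Sox10, a lineage transcription factor, stood at 97.8 ± 7.91 in chloride. The progenitor genes Nes, Cspg4 and Sox2 stood at 339 ± 9.13, 166 ± 12.1 and 53.3 ± 4.78 in chloride and 348 ± 29.6, 163 ± 20.5 and 54.8 ± 5.53 in propionate, and Vim at 2998 ± 208 and 3246 ± 208. The microglia and macrophage markers stood lower, with Cd68 at 3.90 ± 0.741, Lyz2 at 3.12 ± 0.765 and Csf1r at 1.44 ± 0.213 in chloride. By sign 2 of the 4 were higher in propionate (camera adjusted p = 0.631), as were 5 of 5 oligodendrocyte markers (0.271) and 4 of 5 astrocyte markers (0.602). These marker genes were named after their values were seen.

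Interferon-stimulated genes varied between libraries more than between salts. The median of 36 genes, relative to the mean of the 6 libraries on the log2 scale, was -0.03, 0.21 and -0.26 in chloride 1, 2 and 3, and -0.14, 0.05 and 0.15 in propionate 1, 4 and 5. Their estimated correlation was 0.565. Camera called the list as higher without chloride 2 (adjusted p = 6.14e-05), without propionate 1 (0.0278) and with library weights (0.0261), but not with all libraries (0.328, and adjusted p = 0.774 with an estimated correlation). Its direction by camera turned to lower without chloride 3 (median difference -0.03, adjusted p = 0.189) and without propionate 5 (-0.01, 0.853). The 6 abundant structural RNAs, such as the 7SL copies Rn7s1 and Rn7s2, were 6 of 6 higher in propionate by sign (median 0.23, camera adjusted p = 0.0981). Camera called that list with TPM as deposited (0.00961), with mitochondrial and ribosomal RNA left out (0.00752), without chloride 2 (0.0154) and without chloride 3 (0.0222), but not with an estimated correlation (adjusted p = 0.662). Chloride 1 had the lowest median of that list at -0.58 against -0.0029 to 0.24 in the other 5 libraries, and without chloride 1 the median difference was 0.04 (camera adjusted p = 0.793).

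Gm17201 was listed at 0 in each chloride library and at 13.5 to 23.1 TPM in propionate. Reads inside Ankrd52 exons on the other strand do not account for it, because its exon outside them had 18.6 times the coverage of the exon inside (120 against 6.49). The exon outside lies within the extent of an assembled Ankrd52 model on the other strand (128377119 to 128408704). Ankrd52 RNA from outside its exons was therefore not excluded. Assignment of reads to a model in an all-or-none way by the quantifier remains a candidate explanation. Other splits of the 6 libraries held up to 4 genes listed at 0 on one side and at 1 TPM or more on the other, against 1 in the real split. A response of Gm17201 to propionate stays open and was not tested apart from these libraries.

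Chloride 3 and propionate 1, a pair chosen after the data were seen, stood apart from the other 4 libraries, with 3028 of 15509 genes (19.5%) at unadjusted p under 0.05 and 5 past adjusted p 0.05 by limma. They were not alike, since the second principal component put them at opposite ends (25.8 and -27.25). Depth in counted bases does not account for their fewer covered transcripts, which lay -12% and -12.4% from the line of the other 4 libraries against those bases. The pair was defined by that number of transcripts, so this does not test depth as a cause of the gene differences. A length and GC trend is not the whole cause of the gene differences, as 15.6% of 13488 genes still differed after its removal. Of these genes 31 passed adjusted p 0.05 by limma. The share of the same genes before removal was not computed, so whether the trend carries a part is not shown. Reads shared with pseudogenes are not the whole cause either. Of 5033 protein-coding genes with no stretch of 31 bases in common with an annotated pseudogene, 19.4% differed. Of pseudogenes 59.7% lay higher in the pair, of antisense models 64.6% and of assembled loci 62.3%, against 46.9% of protein-coding genes, and since the labels name nothing that these libraries share, no biological explanation was tested.

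The 10 lists called by camera differed by small amounts in one direction each, and none was called with an estimated correlation. That correlation between members was 0.516 for histone genes, 0.412 for nuclear-retained RNAs and 0.313 for ribosomal protein genes. It was -0.0254 for the immediate-early list and 0.0315 to 0.13 for the other called lists. The immediate-early value lay below the preset 0.01, yet the unadjusted camera p of that list rose from 1.03e-06 to 0.00538 with the estimate. Correlation between members thus does not account for that lost call. A call lost in this setting does not by itself show that the members of a list vary together. A length and GC trend could carry part of this, as 6 of the 10 were still called after its removal against 9 with the same genes uncorrected, and medians shrank for histone genes (0.16 to 0.08, interquartile range 0.12 to 0.20 before and 0.03 to 0.12 after), ribosomal protein genes (0.09 to 0.06) and nuclear-retained RNAs (-0.18 to -0.09, -0.28 to -0.04 before and -0.21 to 0.02 after). The deacetylase inhibitor list also lost its call (camera adjusted p = 0.0725). Its median was 0.122 before and 0.0745 after, with interquartile ranges of 0.0281 to 0.135 and 0.0279 to 0.133. The lost calls of glucocorticoid targets (median 0.0866 before and 0.0844 after) and of Wnt, TGF-beta and YAP targets (0.03 and 0.05, already lost at camera adjusted p = 0.0524 uncorrected) do not speak for the trend. For the immediate-early list the trend was not the whole cause, as camera still called it (adjusted p = 0.00189, median 0.11 after removal and 0.12 before, where the call was lost at adjusted p = 0.220 with an estimated correlation). A smaller share of intron-derived RNA may also contribute, but its measure here is indirect. Of the 270 models used, 37 were sense-intronic and 233 were unverified models, whose class does not say that they are intronic. Their median log2 difference was -0.216 relative to protein-coding genes. They lay lower in each propionate library than in each chloride library, narrowly for propionate 5 (-0.09) and chloride 1 (-0.06). Chloride 3 stood highest (0.26), so the size of the difference rests in part on that library. A response to propionate remains open as well.

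The 6 libraries allow 10 splits into equal groups, too few for a share under 0.05. For genes the real split gave 1 and the highest other 4, and 7 of the 10 splits gave as many. For lists called by camera with a preset correlation the real split gave 10 and the highest other 10, and 2 of the 10 splits gave as many. For transcripts the real split gave 13 and the highest other 48, and 9 of the 10 splits gave as many. Other splits that part chloride 3 and propionate 1, as the real split does, gave 0 to 4 genes, 1 to 10 lists and 11 to 17 transcripts. Those that keep them together gave 1 to 4 genes, 3 to 4 lists and 28 to 48 transcripts. The split with 48 transcripts puts chloride 3 and propionate 1 on the same side, which points to a structure of the samples apart from the salts.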
